A study of Homo sapiens with 6 samples.

How the data were processed

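REH cells were treated for 6 h with DMSO or 50 µM S3I-201, with 3 libraries per group, per the labels' protocols. RNA was purified with a column kit and libraries were made by the TruSeq RNA v2 method, which does not mark the strand, so that reads of overlapping genes on opposite strands cannot be told apart. The labels state that the libraries of a group come from independent experiments. Base calling and read processing used hg38 and the tools bcl2fastq 2.19, Trimmomatic, Bowtie2, Picard, featureCounts and DESeq2, per the submitters' processing notes, which name no role or order. The gene annotation, the strand setting of the counting and the model formula were not given in the sources used here.

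The authors' deposited table holds 26364 genes with 4 columns of values, and no column of single libraries was used. The mean normalized count, a signal that is never negative, is the authors' mean over the libraries of counts divided by size factors, per the file headers, whose column names are those of DESeq2. The log2 fold change between the groups was computed by the authors, per the file headers. The p-value and the adjusted p were also computed by the authors, per the file headers. The adjusted p is given for 11912 genes, all with a mean normalized count of at least 10.0, and a Benjamini-Hochberg adjustment of the deposited p-values over these genes came within 0.675% of it. Another 5062 genes had a p-value and a lower mean, 9307 had a mean of 0, and 83 had a fold change and no p-value, which is how the authors' tool DESeq2 by default reports genes with an outlying count. The planned test on counts per library could not be used with these values, so the authors' adjusted p was taken as deposited, as foreseen for that case before the data were examined. The same holds for the groups, gene lists, rule for named genes and most alternatives.

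The direction of the fold change is not stated in the table. Positive values were read as higher in S3I-201, with DMSO as the reference, because DMSO comes first in the alphabet, which sets the default reference in the authors' tool DESeq2. The name of the comparison puts DMSO first too, which can be read either way. The table has no value per library that could settle it. The fold changes appear to have been shrunken towards 0, since genes with a single read had log2 fold changes of only 0.033 to 0.042 in size in the authors' deposited table. Fold changes of weakly expressed genes are therefore understated, and those of abundant genes with a large spread can be understated too. The implied SE is the size of the authors' log2 fold change divided by the normal quantile of the authors' p-value. The implied SE thus belongs to fold changes that appear shrunken, and it can understate the sampling error of unshrunken ones. Its median was 0.18 over tested genes, 0.26 at mean normalized counts of 10 to 100, 0.17 at 100 to 1000 and 0.15 from 1000 upwards. Single abundant genes had a large implied SE too, such as HMOX1 with 0.27 at a mean of 811 and PLK1 with 0.27 at 1481. CYP1A1 had no more at a mean of only 15.8, also with 0.27. A minimum mean of 100 therefore does not exclude understated fold changes.

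Depth was estimated from genes with few reads. Their means were sums of 6 repeated steps, which explained 100% of the 2067 genes with a mean under 0.6 within 1e-07. The 6 steps gave size factors of 1.27, 1.19 and 0.573 for the libraries whose single reads came with positive fold changes and 1.24, 1.02 and 0.948 for those with negative ones. The ratio of the largest to the smallest was 2.21. Scaled by the sum of the mean normalized counts, 11400000, they correspond to about 6600000 to 14500000 counts per library. The steps were not tied to replicate numbers. The 10 most abundant genes held 3.83% of the sum.

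Genes were called at an adjusted p of 0.05. Named by rule were STAT3 with up to 4 JAK-STAT components, the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 100, up to 4 members of each list with the smallest adjusted p, and all STAT3 targets that passed. A list and some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen. The 27 gene lists came from textbook knowledge and share members. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed normal quantile of the authors' p-value, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the 21 lists with at least 5 tested members. An estimated correlation needs values per library, so preset correlations of 0.05 and 0.1 were added. Within each list the p-values were also adjusted over the list alone. Other alternatives were other thresholds, a minimum fold, adjustment without the abundance filter, removal of the median fold change in 20 abundance bins, rank-based camera, camera on fold changes and lists without shared members.

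Symbols were matched to reference tables, with 23795 found as current names, 1466 as older names and 1103 not found. Coordinates are whole-gene spans of the RefSeq annotation of GRCh38.p14, the same assembly as hg38. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data. All 6 size factors were recovered from 12000 simulated genes. With the implied SE of the 11912 tested genes of S3I-201 against DMSO, 95% of simulated log2 changes of 1 and 21% of those of 0.5 were called, with 9 false calls. These changes were on the scale of the deposited fold changes, which appear shrunken, so the shares do not hold for unshrunken changes. In a separate simulation, random normal values were drawn for the 11912 genes, and all members of 3 lists were shifted by the same size. There camera called 3 of 3 shifted lists and 0 of 18 others. Smaller shifts, or shifts of only some members, were not simulated for camera. The simulated genes were independent, so this does not test the preset correlation.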

Results

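RNA-seq libraries were made from REH cells, an established human line of B-cell precursor acute lymphoblastic leukaemia. Cells were kept for 6 h with 50 µM S3I-201, a small molecule directed at STAT3, or with its solvent DMSO as the control. Each of the 2 groups held 3 libraries, which the labels place in independent experiments. Values per gene came from the authors' deposited table, which pools the 6 libraries into a mean normalized count, a log2 fold change, a p-value and an adjusted p. The means of rarely detected genes moved in steps of a single read, and these steps gave 6 size factors from 0.573 to 1.27, or about 6600000 to 14500000 counts per library. Which group served as the reference was not stated. Positive fold changes were read as higher in S3I-201, with DMSO as the reference, and under the opposite reading every direction given here would turn.

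The comparison asks which transcripts changed in REH cells when STAT3 was targeted with the compound. Genes of the oxidative, amino acid and endoplasmic reticulum stress responses were higher with S3I-201, while genes of G2 and mitosis were lower. Of called genes with a mean normalized count of at least 100, OSGIN1 had the largest increase in the authors' deposited table, at 13.9-fold (log2 fold change 3.80, implied SE 0.21, adjusted p = 1.27e-69). OSGIN1 is an oxidative stress-induced growth inhibitor. Among genes with an adjusted p and a mean normalized count of at least 100, the largest decrease belonged to PIF1, a DNA helicase, with a log2 fold change of -2.44 in the authors' deposited table (implied SE 0.24, adjusted p = 1.28e-20). STAT3 itself had a log2 fold change of 0.46 in the authors' deposited table (implied SE 0.18), which did not pass (adjusted p = 0.108).

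Of 11912 genes with an adjusted p, 703 passed 0.05 in the authors' deposited table, 530 of them higher and 173 lower with S3I-201. A change of at least 1 on the log2 scale was reached by 178 of these, 156 higher and 22 lower. The ratio of higher to lower calls moved with abundance, from 33 against 1 at mean normalized counts of 10 to 30 to 53 against 22 above 3000. Among genes with a mean of at least 100, the increases next in size after OSGIN1 in the authors' deposited table were CHAC1 at 6.71-fold, NQO1 at 6.18-fold, TRIB3 and RGS16 at 5.58-fold each, SRXN1 at 5.06-fold and HMOX1 at 4.99-fold. SESN2 at 4.75-fold, SEMA7A at 4.56-fold and TSC22D3, a glucocorticoid-induced leucine zipper protein, at 4.43-fold completed the 10 largest in the authors' deposited table. All fold changes given here appear shrunken towards 0, and those of genes with a large spread can be understated. HMOX1 had an implied SE of 0.27 against 0.17 for NQO1, so the order may differ for unshrunken changes. After PIF1, the decreases next in size among genes with an adjusted p in the authors' deposited table had log2 fold changes of -1.89 for PSRC1, -1.70 for KIF20A, -1.63 for FAM64A, -1.48 for CCNB1 and -1.46 for SAPCD2. CDCA3 at -1.38, UBE2C and PLK1 at -1.28 each and CDC20 at -1.27 followed in the authors' deposited table, and most of these genes encode parts of the mitotic machinery. Among the genes with no p-value, CENPA at -1.54 and DLGAP5 at -1.45, both named after their values were seen, had values of that size in the authors' deposited table. OSGIN1 lies on chromosome 16 from 83953240 to 83966332, PIF1 on chromosome 15 from 64815632 to 64827062 and STAT3 on chromosome 17 from 42313324 to 42388442 (hg38, whole gene).

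**Figure D1:**
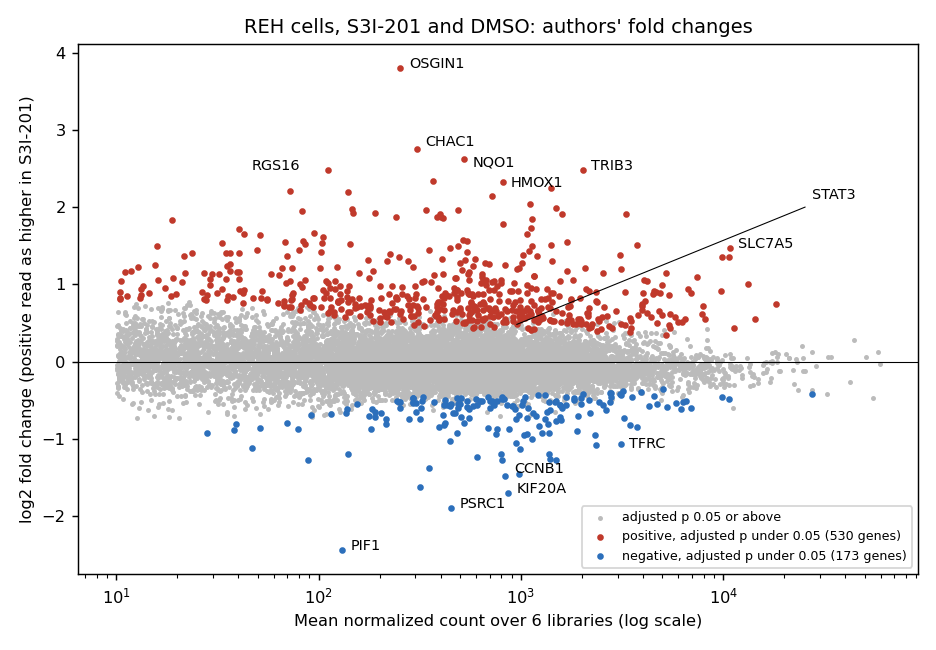
Log2 fold change of each of the 11912 tested genes, with positive read as higher in S3I-201, against the mean normalized count over the 6 libraries on a log scale, both from the authors' deposited table. Red points (530 genes) and blue points (173 genes) had an adjusted p under 0.05, and STAT3 lies among the grey points that did not.

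**Figure D2:**
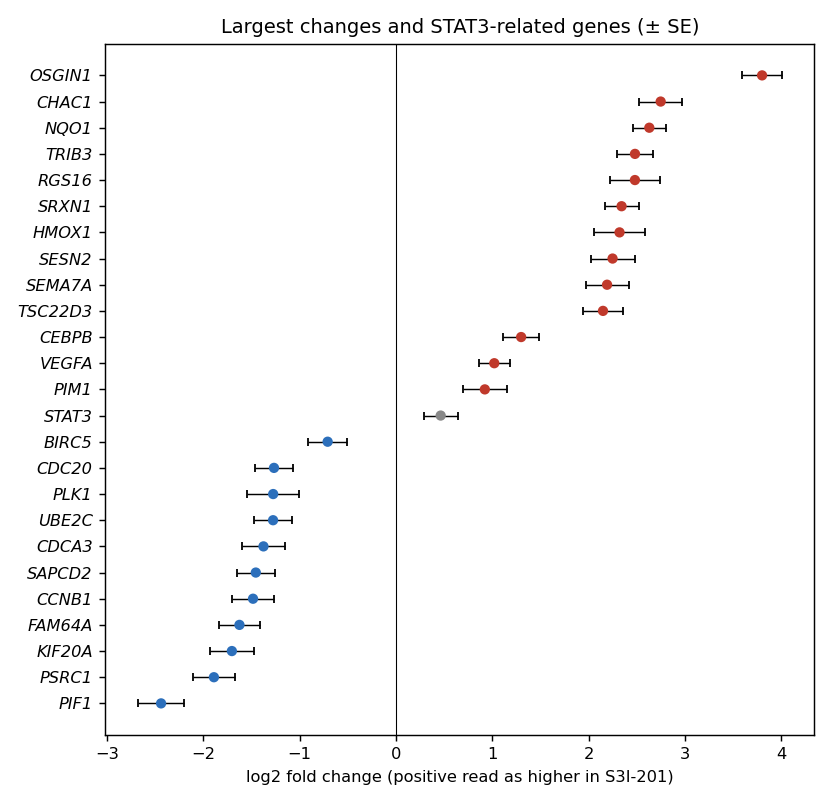
Log2 fold changes from the authors' deposited table for the 10 largest increases, the 10 largest decreases, STAT3 and 4 STAT3 target genes, with bars of 1 implied SE. Values and bars appear shrunken, so the bars can understate the sampling error. Red and blue points had an adjusted p under 0.05, and STAT3 in grey did not at 0.46.

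The response to oxidative stress that NRF2 drives was higher as a group. Of its 22 tested genes 14 were higher and 8 did not pass, with the same 14 calls in number when adjusted over the list alone, and the list stood apart from the other genes (limma's camera, adjusted p = 9.02e-41). NQO1, a quinone reductase, had a log2 fold change of 2.63 in the authors' deposited table (implied SE 0.17, adjusted p = 7.08e-49). SRXN1, which repairs oxidised peroxiredoxins, stood at 2.34 in the authors' deposited table (implied SE 0.18, adjusted p = 6.97e-37), and HMOX1, heme oxygenase, at 2.32 (implied SE 0.27, adjusted p = 1.51e-15).

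Genes of the integrated stress response that ATF4 controls had the largest share of higher calls among the lists tested. Of 36 tested, 34 were higher and 2 did not pass, or 35 higher when adjusted over the list alone, with a median log2 fold change of 1.25 (camera adjusted p = 8.41e-107). CHAC1, which degrades glutathione, reached 2.75 in the authors' deposited table (implied SE 0.22, adjusted p = 9.52e-32), and TRIB3, a pseudokinase, 2.48 (implied SE 0.19, adjusted p = 6.49e-37). JDP2, a transcription repressor, stood at 1.88 and SLC7A5, a carrier of large neutral amino acids, at 1.47 on the log2 scale in the authors' deposited table, the latter with a mean normalized count of 10789. The unfolded protein response of the endoplasmic reticulum had 20 of 22 tested genes higher, 20 also when adjusted over the list alone, and 2 that did not pass, with a median of 1.03 (camera adjusted p = 6.02e-49). DNAJB9 at 1.96, HERPUD1 at 1.91, DNAJC3 at 1.43 and MANF at 1.38 had its smallest adjusted p-values in the authors' deposited table, and all of them act in folding or disposal of proteins of the endoplasmic reticulum.

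In the BCL2 family, 3 of 13 tested genes were higher and 10 did not pass, with the same number when adjusted over the list alone. These were PMAIP1, the pro-apoptotic NOXA, at 1.78, BBC3, the pro-apoptotic PUMA, at 1.32 and BAX at 0.57 in the authors' deposited table, while BCL2 had -0.38 (adjusted p = 0.289). The family as a list passed at the preset correlation of 0.01 (camera adjusted p = 0.0142), not at 0.05 (adjusted p = 0.0562), at 0.1 (adjusted p = 0.124) or with rank-based camera (adjusted p = 0.207). Without the members that other lists also hold it turned to the lower side (adjusted p = 0.914), and all 3 of its higher genes promote apoptosis.

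Immediate early genes, mostly transcription factors induced by growth signals and stress, were higher in 15 of 27 tested and did not pass in 12, or higher in 20 when adjusted over the list alone, with a median of 0.65 (camera adjusted p = 2.15e-17). ATF3 at 1.73, KLF2 at 1.54, JUN at 1.50 and IER5 at 1.31 on the log2 scale led them in the authors' deposited table. Heat shock and protein folding genes were higher in 4 of 18 tested, also 4 when adjusted over the list alone, and the list median was 0.12 (camera adjusted p = 7.06e-04). The 4 were the co-chaperones DNAJB4 at 1.87 and DNAJB1 at 0.49, the collagen chaperone SERPINH1 at 1.19 and HSPA1B at 1.04 in the authors' deposited table. Reads of HSPA1B can be shared with the near-identical HSPA1A, so its value is uncertain.

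Genes of G2 and mitosis were lower as a group. Of 30 tested, 21 were lower and 9 did not pass, or 29 lower when adjusted over the list alone, and the median log2 fold change was -0.84 (camera adjusted p = 5.92e-34). A further 8 members had a fold change and no p-value, as DESeq2, the authors' tool, by default reports genes with an outlying count, against 0.463 on average in gene sets matched on abundance (one-sided permutation p = 1e-05, the smallest that 100000 sets can give). That test was chosen after the 8 were seen. A library in another cell cycle state is a candidate explanation that the pooled values cannot settle. All 38 members had a negative value. KIF20A, a kinesin of cell division, stood at -1.70 (implied SE 0.23, adjusted p = 2.21e-11) and CCNB1, cyclin B1, at -1.48 (implied SE 0.22, adjusted p = 2.31e-09) in the authors' deposited table. UBE2C and CDC20, both of the anaphase-promoting machinery, had -1.28 and -1.27 there, with adjusted p-values of 8.69e-09 and 2.48e-08 in the authors' deposited table. Of genes of the G1/S transition and DNA replication, 3 of 37 tested were higher and 34 did not pass, also with 3 higher when adjusted over the list alone and a median of 0.10. E2F2 at 0.72, CDT1 at 0.53 and MCM5 at 0.51 were the 3 higher genes in the authors' deposited table, and MCM7 had -0.44 (adjusted p = 0.0940). CDT1 did not pass with adjustment over all genes with a p-value (adjusted p = 0.0511). The list passed at a preset correlation of 0.01 (camera adjusted p = 0.0354) and was lost at 0.05 (adjusted p = 0.172), at 0.1 (adjusted p = 0.327) and with camera on fold changes (adjusted p = 0.0683).

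STAT3 target genes were not lower as a group. Of 26 tested, 6 were higher, 1 was lower and 19 did not pass, or 7 higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 0.15 (camera adjusted p = 0.00202). The list was lost at a preset correlation of 0.1 (adjusted p = 0.108) and without the members that other lists also hold (adjusted p = 0.160). Its higher genes in the authors' deposited table were the transcription factor CEBPB at 1.30, the growth factor VEGFA at 1.02, the kinases PIM1 at 0.92 and PIM2 at 0.66, FOS at 0.82 and the RNA-binding ZFP36 at 0.65. The lower gene was BIRC5, survivin, which also acts in mitosis, at -0.71 in the authors' deposited table (implied SE 0.20, adjusted p = 0.0111). MYC, named after its values were seen, had -0.57 at a mean normalized count of 4679 in the authors' deposited table, with no p-value. By the authors' DESeq2 adjusted p, 0 of 24 tested components of the JAK-STAT pathway passed, also 0 when adjusted over the list alone, and 2 had an unadjusted value under 0.05 (camera adjusted p = 0.499). These 2 were STAT3 at 0.46 (adjusted p = 0.108) and PTPN6 at -0.29 (adjusted p = 0.225) in the authors' deposited table. STAT5B had -0.23 (adjusted p = 0.437) in the authors' deposited table, with an unadjusted value above 0.05.

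Genes of ribosome biogenesis and other MYC targets were lower as a list, with a median of -0.32 and negative values in all 38 tested (camera adjusted p = 1.56e-10). Single genes passed in 4 cases, or 13 when adjusted over the list alone. These 4 were RRS1 at -0.59, NOP16 at -0.54, LDHA, lactate dehydrogenase, at -0.46 and WDR43 at -0.42 in the authors' deposited table. NOP16 did not pass with adjustment over all genes with a p-value (adjusted p = 0.0526) or with the abundance trend removed (adjusted p = 0.0608), nor LDHA with the trend removed (adjusted p = 0.0900). Cytosolic ribosomal protein genes had a median of -0.00 that became 0.07 when the abundance trend was removed. By the authors' DESeq2 adjusted p, 0 of 43 passed, also 0 when adjusted over the list alone, and 1 had an unadjusted value under 0.05 (camera adjusted p = 0.973). RPL13A had 0.26, RPS9 0.15, RPL10 0.13 and RPL35 -0.14 on the log2 scale in the authors' deposited table.

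Genes of B-precursor identity were lower in 3 of 38 tested, the same number when adjusted over the list alone, with 35 not past and a median of -0.09. The lower genes were IKZF1, the lymphoid factor Ikaros, at -0.74 (implied SE 0.15, adjusted p = 4.39e-05), the surface protein CD24 at -0.61 and LEF1 at -0.49 in the authors' deposited table, while ERG had -0.41 (adjusted p = 0.0820). The list passed at a preset correlation of 0.01 (camera adjusted p = 0.0106) and not at 0.05 (adjusted p = 0.0949) or 0.1 (adjusted p = 0.228). Its median was -0.03 with the abundance trend removed (camera adjusted p = 0.0449). Cholesterol synthesis genes had a median of -0.19, with STARD4, a sterol carrier, higher at 0.75 and the other 22 of 23 not past in the authors' deposited table. When adjusted over the list alone, 2 were higher and 2 lower, and the list passed at 0.01 (camera adjusted p = 0.0278), not at 0.05 (adjusted p = 0.112) or 0.1 (adjusted p = 0.228). Removal of the abundance trend left a median of -0.15 (camera adjusted p = 0.0471). SQLE at -0.55, HMGCS1 at -0.45 and HSD17B7, which has a pseudogene, at 0.58 did not pass in the authors' deposited table. Nuclear genes of oxidative phosphorylation had a median of -0.12 and passed as a list (camera adjusted p = 0.0103), which was lost at correlations of 0.05 (adjusted p = 0.0926) and 0.1 (adjusted p = 0.228). Their median was -0.07 with the abundance trend removed (camera adjusted p = 0.0449). By the authors' DESeq2 adjusted p, 0 of these 36 genes passed, also 0 when adjusted over the list alone, and 2 had an unadjusted value under 0.05. ATP5G1 at -0.44 and NDUFA2 at -0.35 had the smallest adjusted p-values of this list in the authors' deposited table, at 0.171 and 0.250.

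Glycolysis and hypoxia genes went both ways, with 4 of 32 tested higher and 2 lower, or 4 and 3 when adjusted over the list alone (camera adjusted p = 0.973). ADM, adrenomedullin, at 1.45 and NDRG1 at 1.01 were higher and HK2, hexokinase, at -0.57 was lower in the authors' deposited table, and VEGFA and LDHA belong here too. NF-kB targets had 2 of 21 higher and 1 lower, the same when adjusted over the list alone. The list did not pass (camera adjusted p = 0.0865), except with rank-based camera (adjusted p = 0.0452) and camera on fold changes (adjusted p = 0.0432). They were the chemokine CXCL8 at 1.14, RELB at 0.80 and the inhibitor TNFAIP3 at -0.44 in the authors' deposited table, the last of which did not pass with the abundance trend removed (adjusted p = 0.106). Interferon response genes had 2 of 34 higher, also 2 when adjusted over the list alone (camera adjusted p = 0.542), namely TRIM22 at 0.85 and HERC5 at 0.65 in the authors' deposited table. RNA splicing factors had a median of -0.10, and by the authors' DESeq2 adjusted p 0 of 28 passed, also 0 when adjusted over the list alone, with 5 at an unadjusted value under 0.05. The list did not pass (camera adjusted p = 0.0830), except with rank-based camera (adjusted p = 0.0396). CLK1 had 0.53 (adjusted p = 0.0684, or 0.0389 with the abundance trend removed) and HNRNPDL -0.39 (adjusted p = 0.111) in the authors' deposited table. Of 5 tested replication-dependent histones, 0 passed by the authors' DESeq2 adjusted p and 1 was lower when adjusted over the list alone, HIST1H2BH at -0.71 in the authors' deposited table, which also passed with the abundance trend removed (adjusted p = 0.0429). The histones did not pass as a list (camera adjusted p = 0.746).

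Lists with fewer than 5 tested members were not tested as lists. Of 4 metal response genes, HMOX1 was higher and MT1X at -0.54, MT2A at -0.38 and SLC30A1 at 0.05 did not pass in the authors' deposited table, although MT1X was lower when adjusted over the list alone. Of 4 aryl hydrocarbon receptor targets, NQO1 was higher, also when adjusted over the list alone, and TIPARP at 0.33, AHRR at 0.10 and CYP1A1 at -0.19 did not pass in the authors' deposited table. Markers of other cell types were few, and 0 of 6 passed by the authors' DESeq2 adjusted p, also 0 when adjusted over the list alone and 0 at an unadjusted value under 0.05. They were NKG7 of T and NK cells at a mean normalized count of 13.7, MPO at 978, CSF1R at 127 and ITGAM at 90.4 of myeloid cells, and PDGFRB at 654 and COL1A1 at 40.6 of fibroblasts in the authors' deposited table. Mitochondrially encoded genes were not analysed here.

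**Figure D3:**
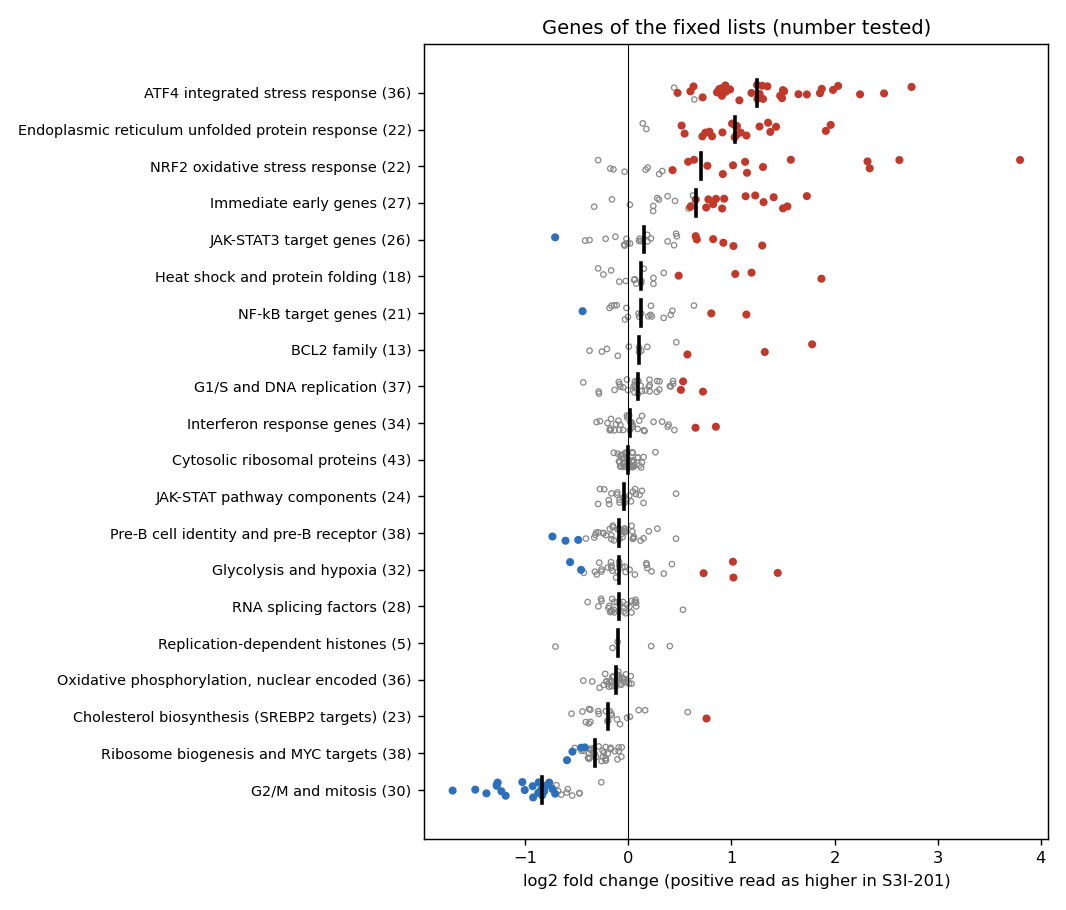
Log2 fold changes from the authors' deposited table for the tested genes of 20 gene lists, with positive read as higher in S3I-201 and the number tested in brackets. Filled points had an adjusted p under 0.05 and black bars mark list medians, which run from -0.84 for G2 and mitosis to 1.25 for the ATF4 integrated stress response.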

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

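The removal of the abundance trend, the preset correlations of 0.05 and 0.1, the removal of shared members and the thresholds over the list alone were chosen after seeing the data. Against 703 calls, 442 genes passed at 0.01 and 178 with a log2 change of at least 1, where fewer genes qualify by construction. Of the higher genes, 156 had that size, and of the lower genes 79 passed at 0.01, 270 at 0.1 and 22 had that size. Adjustment over all genes with a p-value gave 644 calls, and removal of the abundance trend 706, of which 649 were shared in the same direction. Those 706 were 571 higher and 135 lower, against 530 and 173 before. Of 21 lists 14 passed, against 9 at a preset correlation of 0.05 and 8 at 0.1, where the assumed correlation widens the null. Rank-based camera lost the BCL2 family (adjusted p = 0.207) and passed NF-kB targets (adjusted p = 0.0452) and splicing factors (adjusted p = 0.0396), and camera on fold changes lost G1/S (adjusted p = 0.0683) and passed NF-kB targets (adjusted p = 0.0432). The BCL2 family turned to the lower side without shared members (adjusted p = 0.914), since its higher genes left the list, against 0.0142 with them. Of 126 genes taken by the naming rule or chosen later that have an adjusted p, printed or not, 123 stayed on their side of the threshold with adjustment over all genes, where CDT1, FTL and NOP16 were lost. With the trend removed 120 stayed there, LDHA, NOP16 and TNFAIP3 were lost, and CLK1, HIST1H2BH and KEAP1 passed. No paired analysis was possible because the table has no values per library. For the same reason other count models and normalizations, another filter on counts, pseudocounts, an estimated correlation, leaving out each replicate and other splits of the samples were not run. Small changes were often missed at this precision, as 21% of simulated log2 changes of 0.5 were called. The simulated changes were on the scale of the deposited fold changes, which appear shrunken, so the share for unshrunken changes was not tested. Whether depth or the spread between libraries sets this precision was not tested either.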

Other observations

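The genes of the next 2 paragraphs were chosen after their values were seen, and so were the tests on abundant calls, on genes without a p-value and on the share of negative mitotic genes. They are given as single genes, with no count or test of their gene families, and FTH1 and FTL are also members of the NRF2 list. TFRC, the transferrin receptor, had a log2 fold change of -1.07 (adjusted p = 1.84e-07) in the authors' deposited table. The ferritin chains FTH1 and FTL had 0.92 (adjusted p = 2.14e-08) and 0.58 (adjusted p = 0.0426) in the authors' deposited table, and FTL did not pass with adjustment over all genes with a p-value (adjusted p = 0.0599). Both ferritin genes have pseudogenes that can share reads, so these values are uncertain. Single members of the TNF ligand and receptor family past the threshold in the authors' deposited table were FAS at 1.93, TNFSF9 at 1.92, TNFRSF10B at 1.37, TNFSF4 at 1.26, TNFRSF10A at 1.21 and CD70 at 1.08 on the log2 scale. The cytokine genes LIF at 1.52 and CSF1 at 1.32 were higher in the authors' deposited table, at mean normalized counts of 85.7 and 176.

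Also past it in the authors' deposited table were DRAM1, an autophagy modulator, at 1.23, the transcription factor TFE3 at 1.21, GABARAPL1 at 1.11 and the cargo receptor SQSTM1 at 0.95. The transcription factor CREB3L2 had 1.55, the vesicle coat gene SEC24D 1.51 and the translocon gene SEC61A1 0.94 in the authors' deposited table. NFE2L2, which encodes NRF2, had 0.59 (adjusted p = 0.00690) and KEAP1, its inhibitor, 0.38 (adjusted p = 0.0534, or 0.0218 with the abundance trend removed) in the authors' deposited table. IL21R had 1.87 in the authors' deposited table and no p-value.

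More genes were higher than lower, 530 against 173. Of 234 calls with a mean of at least 1000, 68.8% were higher (95% exact interval 62.4 to 74.7). Background reads in weakly expressed genes alone would not give an excess among such abundant genes. The split of abundant calls does not test background among weak genes, where calls were 33 against 1 at means of 10 to 30. Genes with a single read numbered 240, 178 and 147 in the libraries of the positive side and 133, 116 and 145 on the negative side. Background among weak genes therefore stays open. The exact intervals of this paragraph treat genes as independent, so they do not measure the spread between experiments. The median log2 fold change ran only from 0.06 in the lowest abundance bin to -0.07 in the highest. The measured offset with abundance was thus small on the scale of the deposited fold changes. These appear shrunken, so the offset of weakly expressed genes may be understated. The share of genes with positive values ran from 58.9% at means of 10 to 30 to 32.4% above 3000. With this trend removed, 80.9% of 706 calls were higher (77.8 to 83.7). Removing so small a trend could hardly bring the calls to an even split, so that share decides nothing about the offset. The members of the fixed lists alone are argued against by 74.0% of 551 calls in no list (70.2 to 77.7). These calls can still hold unlisted genes of the same responses, so the responses as a whole are not argued against. As a hypothesis, the excess may belong to the treatment, if positive values mean S3I-201, and a global scaling difference stays open as untested.

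Mitotic genes often had a fold change and no p-value, 8 of 38 list members, among them CENPA at -1.54, DLGAP5 at -1.45, CENPF at -1.15 and CCNB2 at -0.62 in the authors' deposited table. Sets of genes matched on abundance held 0.463 on average, which argues against random scatter of outlying counts (one-sided permutation p = 1e-05, the smallest that 100000 sets can give). The test was chosen after this number was seen, so its p describes the pattern and is no independent evidence. One library in another cell cycle state would also leave G1/S genes without p-values, and 3 of 40 were (CDC6, DTL and SLBP) against 0.606 in matched sets (one-sided permutation p = 0.0218). The G1/S test was also chosen after the data were seen. Matched sets take genes as independent, while members of these lists can vary together, so both p-values can be too small. That a library differed in cell cycle state is a candidate explanation only. Which library, and of which group, cannot be read from the table.

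The G2/M list was lower and the G1/S list was not. The abundance trend ran only from 0.06 in the lowest bin to -0.07 in the highest, too little to account for a G2/M median of -0.84. Its removal left a median of -0.78 (95% bootstrap interval -0.93 to -0.69, with list members treated as independent). The small trend had fixed that outcome, so the removal adds no evidence of its own. Fewer cells in G2 and mitosis would lower nearly all members, and 100% of 38 were negative, but lower transcription of these genes per cell predicts that too, and these cannot be told apart without counts of cells by cycle phase. A single library in another cell cycle state, as raised by the missing p-values, stays open here too, since the table has no values per library.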
